A study of Rattus norvegicus with 39 samples.

How the data were processed

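Heart and subcutaneous abdominal white adipose tissue (WAT) of male F344 rats were measured on 39 Affymetrix RAE230 2.0 arrays, 20 of heart and 19 of WAT. Per the labels, the apical part of the heart was homogenized, RNA was extracted with Trizol and RNeasy columns, and 2 ug of total RNA were labelled per array. Animals came from a tissue bank, those with gross tumors were excluded, and the time of day of collection is not given. Restricted animals were housed singly and changed to a fortified diet when restriction began, while ad libitum animals were housed 3 per cage, so housing and diet formula go with restriction.

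The deposited values are GCRMA intensity per probe set for 31099 probe sets, per the labels, with no version of GCRMA given. All values were above 2 and their range was far wider than that of log2 values, so they were read as linear and log2 transformed. The quantiles of the arrays were near equal within a tissue and differed between tissues, and the labels do not say whether both tissues were normalized together. Groups were taken from the labels and no array was left out of the main comparisons. No columns were identical, and the highest correlation between arrays was 0.9968. Median intensity per array ran from 22.9 to 25.7 in heart and from 25.4 to 27.5 in WAT, and the number of arrays limits the precision.

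Probe sets were given gene symbols through the array annotation supplied: 20832 had 1 symbol, 436 had several and 9831 had none, for 14218 distinct symbols. Within a tissue, a probe set was tested if its log2 intensity was at least 4 in at least as many arrays as the smallest group, 6 in heart and 5 in WAT. This left 18096 probe sets in heart and 18749 in WAT, with 10106 and 10238 named genes. For a gene with several probe sets, the probe set with the highest mean was reported.

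Differences were tested per probe set with limma 3.58.1 in R 4.3.3, by linear models over all arrays of a tissue with empirical Bayes moderation and an intensity trend, two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. The comparisons were 28AL against 4AL, 28CR against 28AL and 28CR against 4AL in each tissue. Differences between tissues were tested as interaction terms over all 39 arrays and the 16684 probe sets that passed the filter in both tissues. Probe sets called in both 28AL against 4AL and 28CR against 28AL with opposite signs were counted. Since these comparisons share the 28AL arrays, the count was set beside 100 simulations without true changes, drawn from the residuals of the arrays, and beside splits of the 28AL arrays.

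Gene lists were written from general knowledge, 29 of processes and 15 of cell types, each tested with at least 3 measured members. They were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison, 44 within a tissue and 43 between tissues. Members past the threshold were counted over all probe sets and adjusted over the list alone. Camera with an estimated correlation (statmod 1.5.0) and fry were run beside it.

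The comparisons, lists, tests and the rule for named genes were fixed before the data were examined. For age and restriction in each tissue the rule names the 10 largest increases and 10 largest decreases among called probe sets with a single symbol, if every animal of 1 group lay on the same side of the other group's median. For 28CR against 4AL it names 5 in each direction under that condition, and for the differences between tissues 5 in each direction without it. It adds up to 4 of the members with the largest changes of each called list and a set of 20 genes reported in every comparison within a tissue. Placeholder symbols were passed over. From the list members the rule gives, the text names a part.

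The procedure was tested on simulated data with the real group sizes and 200 changed probe sets. Of probe sets changed by 0.5, 1 and 2 on the log2 scale, the share called was 58.2%, 95.5% and 100% for age in heart, 46.3%, 92.5% and 100% for restriction in heart, and 49.3%, 91% and 98.5% for 28CR against 4AL in heart. In WAT it was 31.3%, 77.6% and 100% for age, 26.9%, 86.6% and 100% for restriction, and 50.7%, 85.1% and 100% for 28CR against 4AL. For the difference in age changes between tissues it was 28.4%, 76.1% and 97%, and for that in restriction changes 20.9%, 79.1% and 95.5%.

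Arrays of different groups and tissues share animal numbers in the labels. Correlations of the centred profiles of arrays with 1 number did not establish that the numbers pair arrays, so the main fits use no block. The alternatives were no intensity filter, a filter at log2 of 6, no intensity trend, robust moderation, quantile normalization, equal array medians, array weights, a fit of only the groups compared, 1 probe set per gene, the mean of the probe sets of a gene, a minimum change of 1.5-fold, a replicate block, a block of array numbers, splits of the 28AL arrays, and leaving out each array. After the data were seen, a skeletal muscle term for WAT and fits without arrays of doubt were added. The skeletal muscle term is the mean log2 intensity of the skeletal muscle markers per array. The arrays of doubt were heart 4AL animal 18, with a median correlation of 0.967 with its group, heart 28CR animal 8, with adipocyte transcripts (Adipoq at log2 of 5.72), WAT 28CR animal 6, with skeletal muscle transcripts and a correlation of 0.917, and WAT 28AL animal 6, with cardiac transcripts (Myh6 at log2 of 11.67).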

Results

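Gene expression was measured in the heart and the subcutaneous abdominal white adipose tissue (WAT) of male F344 rats, an inbred laboratory strain. The 3 groups were animals of 4 months fed ad libitum (4AL), animals of 28 months fed ad libitum (28AL) and animals of 28 months under caloric restriction (28CR). Restricted animals received 60% of the ad libitum intake from 4 months of age. Heart was measured in 6 4AL, 7 28AL and 7 28CR animals, and WAT in 7 4AL, 5 28AL and 7 28CR animals, with 1 array per animal and tissue. The labels give group body weights of 253 ± 8 g for 4AL, 382 ± 20 g for 28AL and 288 ± 7 g for 28CR animals, without the kind of error. Median probe set intensity ran from 22.9 to 25.7 across the 20 heart arrays and from 25.4 to 27.5 across the 19 WAT arrays. Of the 31099 probe sets, between 56.1% and 59% per array had a log2 intensity of at least 4, and the number of arrays limits the precision of every value. All changes are differences of group means in log2 intensity ± SE, with the number of arrays given above, and "rose", "fell" and "changed" are used only for probe sets or gene lists past an adjusted p of 0.05 in limma. Counts of list members are over all probe sets tested unless given as adjusted over the list alone.

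The counts for the comparisons within the tissues are shown in the plot of called probe sets.

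**Figure D1:**
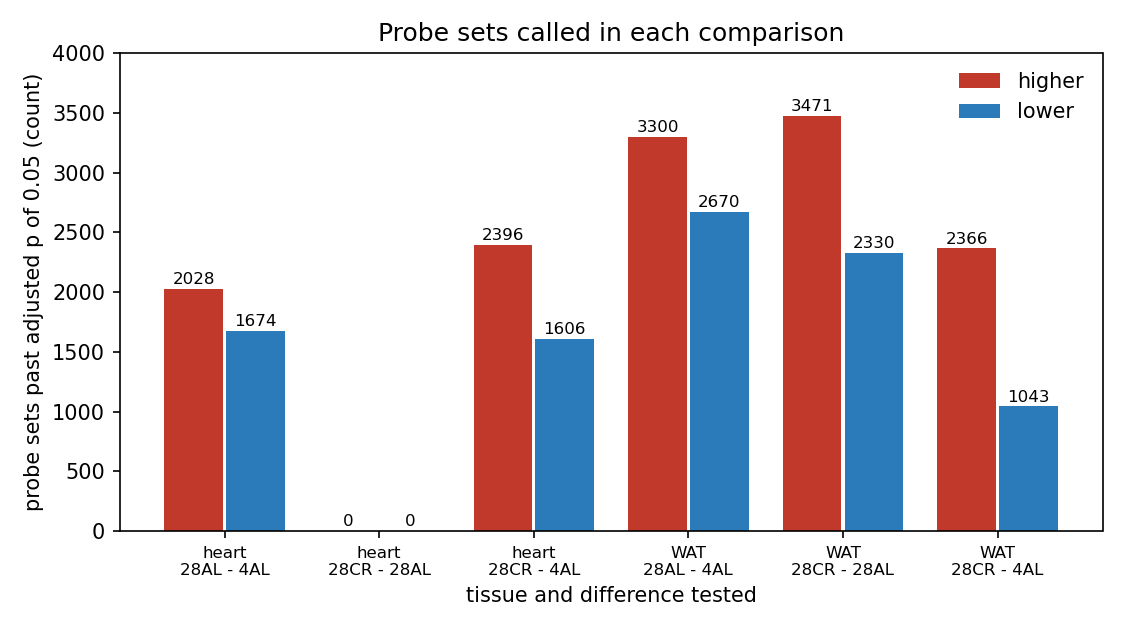
Number of probe sets past an adjusted p of 0.05 in each comparison of groups (vertical axis, count from 0), higher (red) or lower (blue) in the group named before the minus sign. Heart 28CR against 28AL has 0 in both directions, and the largest count is the 3471 probe sets higher in 28CR than in 28AL WAT.

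The comparison of 28AL with 4AL hearts addressed how age changes expression in the heart of animals fed ad libitum. Transcripts of the natriuretic peptides and of slow myosin rose. Nppa, which encodes atrial natriuretic peptide, rose from a log2 intensity of 10.61 ± 0.38 (SD, n = 6) to 13.86 ± 0.37 (SD, n = 7), a difference of 3.25 ± 0.16. Myh7, the beta myosin heavy chain of the fetal rodent ventricle, rose by 1.72 ± 0.12, and Nppb, which encodes B-type natriuretic peptide, rose by 1.15 ± 0.27. Myh6, the alpha myosin heavy chain of the adult rodent ventricle, fell by 0.47 ± 0.08. Of the 15 measured members of the list of fetal and stress genes of the heart, 8 rose and 0 fell (9 and 0 adjusted over the list alone). That list was higher by the camera test (adjusted p = 8.4e-05; adjusted p = 0.19 with an estimated correlation). Atrial markers, a list that shares Nppa and other members with it, moved with it, with a median of 0.78, 4 of 7 up and 0 down (4 and 1; adjusted p = 0.0451; adjusted p = 0.316 with an estimated correlation).

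Cnpy1 (4.02 ± 0.15) and Bex1 (4.00 ± 0.16) rose in heart with age, as did Gpr15lg (3.55 ± 0.76), the lipoxygenase gene Alox15 (3.41 ± 0.66), Ccn5 (3.34 ± 0.37), the leukocyte surface gene Cd52 (3.13 ± 0.39), the matrix glycoprotein gene Thbs4 (3.07 ± 0.46), Chi3l1 (2.94 ± 0.20) and Alas2 (2.92 ± 0.25), which encodes the erythroid enzyme of heme synthesis. Kcnk2, which encodes a potassium channel opened by stretch, had the largest decrease, from 6.26 ± 0.14 (SD, n = 6) to 4.03 ± 0.44 (SD, n = 7). Baalc fell by 2.00 ± 0.29, Cd7 by 1.93 ± 0.28, Wfdc1 by 1.70 ± 0.21, Fxyd3 by 1.61 ± 0.28 and the alpha adrenergic receptor gene Adra1d by 1.61 ± 0.23. Aqp7, a glycerol channel gene, fell by 1.52 ± 0.34, Ddit4l by 1.5 ± 0.22, Agpat3 by 1.39 ± 0.16 and Dhrs7c by 1.35 ± 0.23. In each of these genes, every animal of at least 1 of the groups lay on the same side of the median of the other group. The 4AL means of Cnpy1, Gpr15lg, Alox15, Ccn5 and Cd52 and the 28AL mean of Adra1d lay below the filter at 4, so the sizes of these changes are set against background and are not ranked.

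Matrix genes of the aged heart changed unevenly. Postn, which encodes the matricellular protein periostin, rose by 2.34 ± 0.28, Col8a1 by 1.57 ± 0.22 and the proteoglycan gene Bgn by 1.38 ± 0.16, whereas the differences for the fibrillar collagen genes Col1a1 (-0.06 ± 0.17) and Col3a1 (-0.15 ± 0.14) did not pass the test. Among genes of matrix remodelling, Ccn2 rose by 1.76 ± 0.19, Ltbp2 by 1.67 ± 0.30, Loxl1 by 1.27 ± 0.17 and Timp1, an inhibitor of matrix metalloproteinases, by 1.14 ± 0.27. In the list of collagens and structural matrix 10 of 26 members rose and 1 fell (10 and 2 adjusted over the list alone), and in the remodelling list 10 of 20 rose and 0 fell (11 and 0). Both lists were higher, with adjusted p = 0.0369 and 0.000378 (adjusted p = 0.518 and 0.285 with an estimated correlation). Fibroblast and stromal markers moved with them, with a median of 0.39, 7 of 12 up and 0 down (7 and 0; adjusted p = 0.00367; adjusted p = 0.298 with an estimated correlation).

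Immune transcripts rose in the aged heart over several lists. Of 16 macrophage and monocyte markers 15 rose and 0 fell, among them Fcgr3a (1.75 ± 0.38), Gpnmb (1.42 ± 0.22), the scavenger receptor gene Cd163 (1.32 ± 0.19) and Cd68 (1.00 ± 0.17). Of 12 complement and acute phase genes 10 rose and 0 fell, including C3 (2.23 ± 0.31) and the ceruloplasmin gene Cp (1.73 ± 0.18). In the interferon list 12 of 22 rose and 0 fell (14 and 0 adjusted over the list alone), with Rsad2 at 1.54 ± 0.27, Irf7 at 1.34 ± 0.17 and Mx1 at 1.24 ± 0.21. Of 21 inflammatory mediators 12 rose and 0 fell (16 and 0), with the B cell chemokine gene Cxcl13 at 1.94 ± 0.21 and the adhesion molecule gene Vcam1 at 1.04 ± 0.18. These 4 lists were higher, with camera adjusted p = 9.88e-10 for macrophage markers, 7.41e-07 for complement, 7.64e-08 for interferon and 4.47e-06 for inflammatory mediators, and adjusted p = 0.19 with an estimated correlation for each. The counts for macrophage and complement genes adjusted over the list alone were also 15 and 10. Markers of blood cells moved with these lists: all 6 erythroid and blood markers rose, with Slc4a1, the anion exchanger of red cells, at 2.69 ± 0.46 (list adjusted p = 4.16e-07; adjusted p = 0.166 with an estimated correlation). The neutrophil genes S100a9 (2.71 ± 0.36) and S100a8 (1.99 ± 0.31) and the cytotoxic genes Prf1 (2.77 ± 0.49) and Gzma (1.81 ± 0.49) rose as well. Cd74, the invariant chain of MHC class II, fell by 0.44 ± 0.15, a call that ended in 10 of the 20 fits without a single array, with the highest adjusted p of 0.0893 without 4AL animal 22, and also with no intensity filter (0.0687) and no intensity trend (0.0527).

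Genes of mitochondrial energy metabolism fell with age in heart. In the fatty acid oxidation list 18 of 26 members fell and 0 rose (22 and 1 adjusted over the list alone), among them the peroxisomal enzyme gene Ehhadh (-1.27 ± 0.18), the uncoupling protein gene Ucp3 (-1.27 ± 0.35), Acadvl (-0.87 ± 0.14) and Hadh (-0.83 ± 0.16). In the list of the tricarboxylic acid (TCA) cycle 15 of 18 fell and 0 rose (17 and 0), with Suclg1 at -0.49 ± 0.08, Sucla2 at -0.48 ± 0.08 and Pdhb at -0.46 ± 0.08. In the list of oxidative phosphorylation 21 of 40 fell and 0 rose (27 and 0), with Ndufa9 at -0.52 ± 0.09 and Ndufs1 at -0.44 ± 0.08. All 3 lists were lower with adjusted p = 4.28e-10 each (adjusted p = 0.194, 0.19 and 0.194 with an estimated correlation). Sarcomere and calcium handling genes were lower too, with 14 of 22 down and 0 up (16 and 0), among them the muscle creatine kinase gene Ckm at -0.65 ± 0.14 (list adjusted p = 6.48e-08; adjusted p = 0.194 with an estimated correlation). Pdk4, which encodes a kinase that inhibits pyruvate dehydrogenase, differed by -0.69 ± 0.29 and did not pass the test.

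Several single genes of signalling and stress also rose in the aged heart. Kcne1, a potassium channel subunit gene with a 4AL mean of 2.90 below the filter, rose by 1.80 ± 0.28, the glutathione transferase gene Gsta1 by 2.44 ± 0.11, Srxn1 by 1.17 ± 0.13 and the metallothionein gene Mt2A by 1.88 ± 0.26. Of 19 immediate early genes 9 rose and 0 fell (13 and 0 adjusted over the list alone), including Myc at 1.54 ± 0.20 and Nr4a1 at 1.05 ± 0.18 (list adjusted p = 1.65e-05; adjusted p = 0.19 with an estimated correlation). The myelin genes Cnp (1.05 ± 0.11) and Mbp (1.04 ± 0.18) and the fibroblast markers Fbln1 (1.49 ± 0.22) and Pi16 (1.40 ± 0.23) rose. Per2, a repressor of the circadian clock, rose by 1.59 ± 0.22 and the clock output gene Dbp by 1.09 ± 0.30. Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 0.44 ± 0.15, a call that ended in 11 of the 20 fits without a single array, with the highest adjusted p of 0.103 without 4AL animal 18. The call for Cdkn1a also ended under 5 other settings, among them the mean of its probe sets (adjusted p = 0.219) and the fit without the heart arrays of 4AL animal 18 and 28CR animal 8 (0.115). Differences did not pass the test for Fasn (0.28 ± 0.21), which passed without 28CR animal 8 (adjusted p = 0.036), or Pparg (-0.26 ± 0.15), and Cdkn2a, Lep, Adipoq, Scd and Ucp1 did not pass the intensity filter in heart and have no test in any heart comparison.

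In limma, 3702 of 18096 probe sets differed between 28AL and 4AL hearts, 2028 higher and 1674 lower, covering 1471 named genes up and 1111 down. The share of higher probe sets was 54.8%, and 48.7% with equal array medians. Of these probe sets 368 were higher and 74 lower by at least 2-fold. Of the 44 gene lists, 28 were called by camera, 17 up and 11 down, and 0 of them were called with an estimated correlation. Blood and immune cells are part of the tissue measured, so the values do not separate changes in cell numbers from changes within cells.

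**Figure D2:**
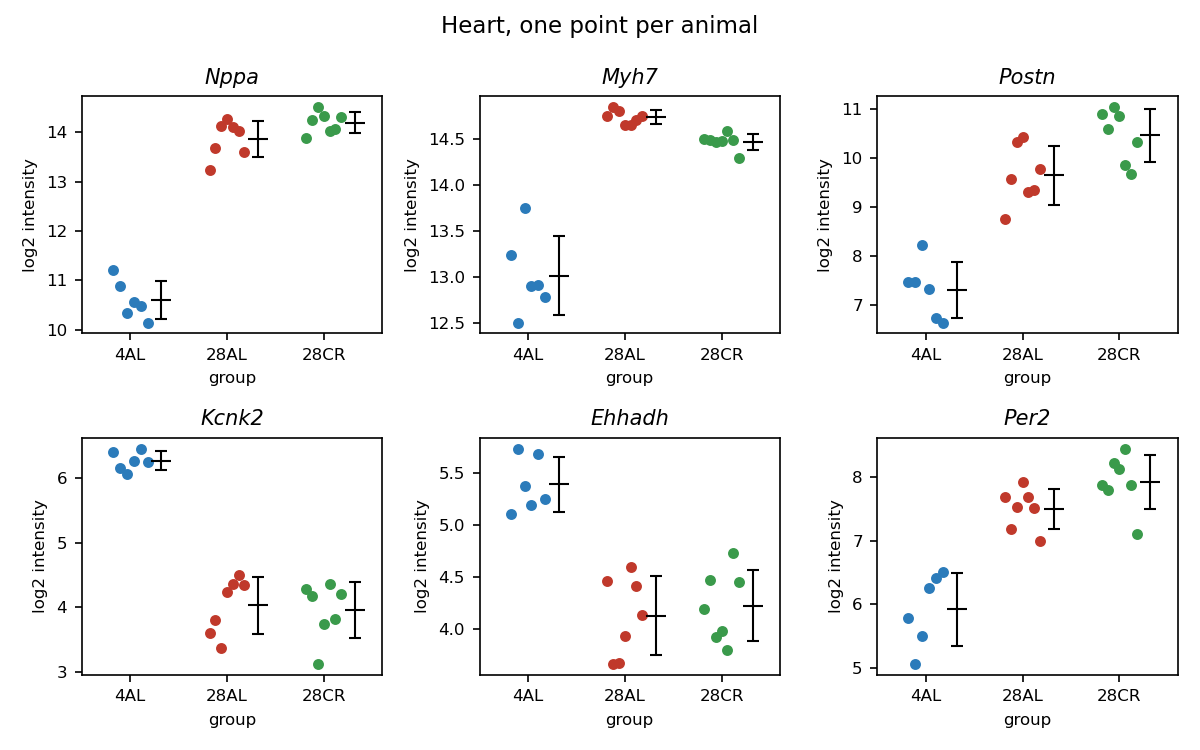
Log2 intensity in heart of 6 genes, with 1 point per animal and the mean ± SD of each group (6 4AL, 7 28AL and 7 28CR animals). Nppa, Myh7, Postn and Per2 were higher and Kcnk2 and Ehhadh lower in both groups of 28 months than in 4AL animals.

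The comparison of 28CR with 28AL hearts addressed what caloric restriction changes in the aged heart. No gene passed the test, and the values that follow are differences without a call. The lowest adjusted p, 0.136, belonged to Krt19, a keratin of epithelial and mesothelial cells, which differed by -1.26 ± 0.22 and passed with array weights (0.0309). Further markers of the mesothelium, the cell layer that lines the pericardial cavity, were Msln (-1.53 ± 0.33) and Lrrn4 (-0.98 ± 0.23). The list of 4 mesothelial markers, of which 1 is also in another list, was lower with a median of -1.12, 0 members called over all probe sets and 3 lower adjusted over the list alone. Its call by camera (adjusted p = 1.1e-07) was the only list call in any comparison that held with an estimated correlation (adjusted p = 0.00704). Msln had a mean log2 intensity of 5.23 ± 0.65 (SD, n = 7) in 28AL and 3.70 ± 0.74 (SD, n = 7) in 28CR hearts, and Krt19 4.17 ± 0.54 (SD, n = 7) and 2.91 ± 0.32 (SD, n = 7), so both differences are set against background below the filter at 4.

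Matrix genes had small positive differences between 28CR and 28AL hearts, with Postn at 0.82 ± 0.27, Col3a1 at 0.45 ± 0.14, Col1a1 at 0.40 ± 0.16 and Timp1 at 0.62 ± 0.26. The list of collagens and structural matrix was higher with a median of 0.27, 0 of 26 members called and 5 higher and 1 lower adjusted over the list alone (adjusted p = 4.29e-05; adjusted p = 0.644 with an estimated correlation). The interferon list was lower with a median of -0.21, 0 of 22 members called and 0 adjusted over the list alone (adjusted p = 7.24e-07; adjusted p = 0.43 with an estimated correlation), with Irf7 at -0.52 ± 0.16. Beside it the 6 erythroid and blood markers were lower with a median of -0.43 and the 5 neutrophil and mast cell markers with a median of -0.29, each with 0 members called and 0 adjusted over the list alone (adjusted p = 0.00366 and 0.00768; adjusted p = 0.595 and 0.399 with an estimated correlation). Cdk1, a kinase of the cell cycle, differed by 0.78 ± 0.35 and Trib3 by 0.35 ± 0.16. Of the other genes reported in each comparison, Nppa differed by 0.33 ± 0.16, Nppb by 0.38 ± 0.26, Myh6 by 0.17 ± 0.08, Myh7 by -0.27 ± 0.12, Pdk4 by -0.58 ± 0.28 and Per2 by 0.42 ± 0.21. Fasn differed by 0.35 ± 0.20, and by 0.10 without 28CR animal 8, an array with adipocyte transcripts (Adipoq at 5.72). Cd68 (0.23 ± 0.17), Cd74 (-0.09 ± 0.14), Cdkn1a (0.06 ± 0.15), Dbp (0.17 ± 0.28) and Pparg (0.17 ± 0.15) differed by less.

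Camera called 13 of 44 lists between 28CR and 28AL hearts, 7 up and 6 down, and 1 of them with an estimated correlation. Among those up were the lists of cell cycle (median 0.26), fetal and stress (0.20) and ER stress genes (0.19), with adjusted p = 0.00408, 0.0271 and 0.00287 (adjusted p = 0.817, 0.768 and 0.644 with an estimated correlation). Each had 0 members called, and adjusted over the list alone there were 0 for cell cycle, 0 for fetal and stress genes, and 5 higher and 1 lower for ER stress. Of 18096 probe sets, limma called 0 in this comparison, and 1396 had an unadjusted p under 0.05, against 905 that uniform p values would give. Leaving out 28AL animal 8 gave 2 calls, leaving out 28CR animal 6 or 28CR animal 11 gave 1, and array weights gave 3. In simulated data of this comparison, 46.3% of probe sets changed by 0.5 on the log2 scale, 92.5% of those changed by 1 and 100% of those changed by 2 were called.

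The comparison of 28CR with 4AL hearts addressed whether hearts of restricted animals of 28 months differ from those of young animals. Thbs4 rose by 4.13 ± 0.46, Bex1 by 3.96 ± 0.16, Cnpy1 by 3.85 ± 0.15, Gpr15lg by 3.63 ± 0.76 and Nppa by 3.58 ± 0.16. Cd7 fell by 2.38 ± 0.28, Kcnk2 by 2.30 ± 0.19, Fxyd3 by 1.91 ± 0.28, Baalc by 1.89 ± 0.29 and Adra1d by 1.75 ± 0.23. The means of Cnpy1, Gpr15lg and Kcne1 in 4AL and of Cd7, Kcnk2 and Adra1d in 28CR hearts lay below the filter, so these sizes are set against background. Postn rose by 3.16 ± 0.28, Col8a1 by 1.86 ± 0.22, Bgn by 1.62 ± 0.16, Ccn2 by 1.95 ± 0.19, Timp1 by 1.76 ± 0.27 and Kcne1 by 2.90 ± 0.28. The 5 largest increases and 5 largest decreases met the same condition on single animals as the changes with age. Nppb rose by 1.53 ± 0.27 and Myh7 by 1.45 ± 0.12, and Myh6 fell by 0.31 ± 0.08. Of 7 atrial markers 4 rose and 1 fell (4 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.0534).

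Genes of fatty acid oxidation fell between 4AL and 28CR hearts in 19 of 26 members with 0 up (20 and 0 adjusted over the list alone), among them Ucp3 (-1.67 ± 0.35), Pdk4 (-1.28 ± 0.29), Ehhadh (-1.17 ± 0.18) and Hadh (-0.90 ± 0.16). Macrophage markers rose in 14 of 16 members with 0 down (15 and 0), with Gpnmb at 1.61 ± 0.22, Cd163 at 1.37 ± 0.19 and Cd68 at 1.23 ± 0.17. Beside them 5 of 6 erythroid and blood markers rose and 0 fell (5 and 0), with Alas2 at 2.45 ± 0.25 and Slc4a1 at 2.30 ± 0.46. Cell cycle genes rose in 18 of 22 members with 0 down (19 and 0), with Cdk1 at 1.72 ± 0.37, Prc1 at 1.37 ± 0.30 and the cyclin gene Ccnb2 at 1.22 ± 0.27. Camera called these 4 lists, with adjusted p = 7.21e-12, 4e-09, 4.6e-05 and 1.54e-06 in that order (adjusted p = 0.228, 0.228, 0.228 and 0.277 with an estimated correlation). Per2 rose by 2.01 ± 0.22, Dbp by 1.26 ± 0.30, and Cd74 fell by 0.52 ± 0.15. Cdkn1a rose by 0.50 ± 0.15 and Fasn by 0.63 ± 0.21. The call for Cdkn1a ended without 4AL animal 18 (adjusted p = 0.0548) and for the mean of its probe sets (0.0719). The change of Fasn was 0.38 without 28CR animal 8, an array with adipocyte transcripts (Adipoq at 5.72), and its call ended in 5 of 20 fits without a single array (highest adjusted p of 0.0706 without 4AL animal 20) and with no filter (0.0604), quantile normalization (0.0543) or only these groups in the fit (0.0786). Col1a1 (0.34 ± 0.17), Col3a1 (0.30 ± 0.14) and Pparg (-0.09 ± 0.15) did not pass the test, and Col3a1 passed with array weights (0.0321).

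Limma called 4002 of 18096 probe sets between 28CR and 4AL hearts, 2396 higher and 1606 lower. The share of higher probe sets among the calls, 59.9%, was 47.1% when arrays were scaled to equal medians. Of 44 lists, 23 were called by camera and 0 of these with an estimated correlation.

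The comparison of 28AL with 4AL WAT addressed how age changes expression in adipose tissue. Enzymes of fatty acid and triglyceride synthesis fell together. Pnpla3 fell by 5.15 ± 0.72, the fatty acid elongase gene Elovl6 by 4.22 ± 0.66, the malic enzyme gene Me1 by 3.53 ± 0.57, and Scd, which encodes stearoyl-CoA desaturase, by 3.26 ± 0.54. Fasn, the fatty acid synthase gene, fell from a log2 intensity of 13.50 ± 0.46 (SD, n = 7) to 9.95 ± 1.09 (SD, n = 5), a difference of -3.55 ± 0.35. Of the 24 measured members of the list of lipogenesis 23 fell and 0 rose, with a median of -1.69, and the counts adjusted over the list alone were also 23 and 0 (adjusted p = 1.08e-15; adjusted p = 0.164 with an estimated correlation).

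Cholesterol synthesis genes fell in 17 of 19 members with 0 up (17 and 1 adjusted over the list alone), including Tm7sf2 (-1.94 ± 0.39), Dhcr7 (-1.73 ± 0.35), Nsdhl (-1.62 ± 0.34) and Acat2 (-1.57 ± 0.37). The mitochondrial pyruvate carrier gene Mpc1 fell by 1.80 ± 0.30, Pdhb by 1.52 ± 0.30 and the pyruvate carboxylase gene Pc by 1.16 ± 0.27, and 17 of 18 members of the TCA cycle list fell with 0 up (17 and 0). In the list of oxidative phosphorylation 22 of 39 fell and 0 rose (26 and 0), with Ndufs1 at -0.72 ± 0.12 and Sdhb at -0.60 ± 0.13. Slc2a4, the glucose transporter that responds to insulin, fell by 1.55 ± 0.28, and 13 of 20 members of the glycolysis list fell with 0 up (15 and 0). Camera called the 4 lists with adjusted p = 1.41e-07, 1.01e-08, 1.35e-08 and 1.59e-06 in that order (adjusted p = 0.224, 0.164, 0.244 and 0.164 with an estimated correlation). Skeletal muscle markers moved with these lists, and with the mean of those markers per array as a term of the fit 6 of the 20 glycolysis members fell, with a median of -0.40 against -0.64 without it.

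Lep, the leptin gene, fell by 2.50 ± 0.42, Ucp1, the uncoupling protein gene of thermogenic adipocytes, by 3.38 ± 0.79, the beta 3 adrenergic receptor gene Adrb3 by 1.84 ± 0.22 and Apod by 2.01 ± 0.56, whereas Apoe rose by 2.26 ± 0.24. In 28AL animals the means of Ucp1 (2.44), Apod and Tm7sf2 lay below the filter at 4, so the sizes of these changes are set against background. In the thermogenic list 4 of 9 members fell and 0 rose (5 and 1 adjusted over the list alone; adjusted p = 0.0174; adjusted p = 0.164 with an estimated correlation). Adipoq (-0.04 ± 0.08) and Pparg (0.08 ± 0.16), genes of the mature adipocyte, did not pass the test, while the list of adipocyte markers was lower with a median of -0.16, 5 of 11 down and 1 up (5 and 1; adjusted p = 0.0382; adjusted p = 0.224 with an estimated correlation). Collagen genes fell, with Col1a1 at -2.75 ± 0.39, Col1a2 at -2.31 ± 0.26, Lum at -1.96 ± 0.28 and Col3a1 at -1.88 ± 0.24. In the list of collagens and structural matrix 13 of 27 fell and 1 rose (13 and 1; adjusted p = 5.66e-07; adjusted p = 0.224 with an estimated correlation). Fibroblast and stromal markers moved with the collagens, with a median of -0.87, 7 of 12 down and 1 up (7 and 1; adjusted p = 0.000899; adjusted p = 0.244 with an estimated correlation).

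Genes of cytotoxic lymphocytes rose in aged WAT, with the granzyme genes Gzmb at 3.80 ± 0.52 and Gzma at 3.51 ± 0.54, Nkg7 at 3.55 ± 0.68, the perforin gene Prf1 at 3.40 ± 0.60 and the chemokine gene Ccl5 at 3.34 ± 0.60. Gzmb had a log2 intensity of 4.44 ± 0.21 (SD, n = 7) in 4AL and 8.25 ± 1.33 (SD, n = 5) in 28AL animals, and the 4AL means of Gzma and Nkg7 lay below the filter. Of 15 T cell and NK cell markers 14 rose and 0 fell (14 and 0 adjusted over the list alone; adjusted p = 1.35e-08; adjusted p = 0.164 with an estimated correlation). The macrophage genes Gpnmb (2.40 ± 0.37), Fcgr3a (1.72 ± 0.37) and Cd53 (1.62 ± 0.17) rose, and 11 of 16 macrophage markers rose with 1 down (12 and 1; adjusted p = 4.36e-05; adjusted p = 0.224 with an estimated correlation). MHC and antigen presentation genes rose in 14 of 17 members with 0 down (16 and 0), with the class II genes RT1-Da at 1.23 ± 0.20 and RT1-Bb at 1.19 ± 0.16 (adjusted p = 1.85e-06; adjusted p = 0.258 with an estimated correlation). With the skeletal muscle term the members that rose numbered 7 for macrophage markers, with a median of 0.56 against 0.90 without it, and 5 for MHC genes, with a median of 0.65 against 0.84. Jchain, a gene of plasma cells, rose by 2.89 ± 0.63, the B cell gene Blnk by 1.20 ± 0.15, and the endothelial genes Vwf by 1.10 ± 0.19 and Emcn by 0.89 ± 0.14. Cd68 (0.94 ± 0.26), Cd74 (0.86 ± 0.20), C3 (2.45 ± 0.66) and Timp1 (0.67 ± 0.23) rose, and with the skeletal muscle term these calls ended (adjusted p = 0.297, 0.0608, 0.0546 and 0.56). The change was then smaller for Cd68 (0.39 ± 0.27), Cd74 (0.65 ± 0.25) and Timp1 (0.21 ± 0.24), whereas C3 (2.23 ± 0.84) kept most of it with a larger error. Without 28AL animal 8 the change of C3 was 1.56. The call for Timp1 also ended in 6 of 19 fits without a single array, with the highest adjusted p of 0.118 without 28AL animal 9.

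Transcripts of skeletal muscle fell in WAT with age. The actin gene Acta1 fell by 7.68 ± 1.62, the myosin light chain genes Myl11 by 6.86 ± 1.73 and Myl1 by 6.25 ± 1.37, Tnnc2 by 6.79 ± 1.63, Actn3 by 5.94 ± 1.62, Myh4 by 5.90 ± 1.55, the calcium pump gene Atp2a1 by 5.79 ± 1.63, Tnnt3 by 5.24 ± 1.46 and Ckm by 5.09 ± 1.63. Of these, Acta1, Myl11, Tnnc2, Actn3, Myh4, Atp2a1 and Tnnt3 had 28AL means below the filter, so their sizes are set against background and are not ranked. Acta1 ran from 7.48 to 14.35 in the 7 4AL arrays, from 2.83 to 5.17 in the 5 28AL arrays and from 3.28 to 14.73 in the 7 28CR arrays, with 14.73 in animal 6 and 10.41 in animal 7. Of 17 skeletal muscle markers 15 fell and 0 rose (16 and 0 adjusted over the list alone; adjusted p = 9.98e-07; adjusted p = 0.275 with an estimated correlation). The call for Ckm ended without 28AL animal 9 (adjusted p = 0.0525). With the skeletal muscle term the differences were -0.35 for Actn3, -0.58 for Myh4, -0.18 for Atp2a1, -0.21 for Tnnt3 and 0.34 for Ckm, and these 5 calls ended. All 5 are among the markers whose mean is that term, so it takes out their change by construction.

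Transcripts of cardiac muscle moved the other way in aged WAT. Myh6 rose by 3.53 ± 0.57, Tnni3 by 2.55 ± 0.58 and Tnnt2 by 2.41 ± 0.61, the last pair encoding cardiac troponins. Myh6 had a log2 intensity of 5.19 ± 0.66 (SD, n = 7) in 4AL and 8.72 ± 1.85 (SD, n = 5) in 28AL WAT, with 11.67 in 28AL animal 6. Without that animal the changes were 2.79 for Myh6, 1.61 for Tnni3 and 1.58 for Tnnt2. Of 9 cardiomyocyte markers, all of which are also in another list, 4 rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.0274; adjusted p = 0.415 with an estimated correlation). Nppa (0.29 ± 0.25) and Myh7 (-1.03 ± 1.23) did not pass the test, and with the skeletal muscle term Myh7 was 2.99 higher. The mean of the skeletal muscle markers was 4.01 ± 0.13 (SD, n = 5) in 28AL and 8.89 ± 2.74 (SD, n = 7) in 4AL WAT. The value of 2.99 therefore rests on the slope in the 4AL and 28CR arrays, carried down to the 28AL level. The lipase gene Pnliprp2 (4.50 ± 0.93), the carboxypeptidase gene Cpa1 (4.11 ± 0.28), the neuronal genes Stmn2 (4.04 ± 0.30) and Snap25 (3.49 ± 0.35), and Siglec10 (3.38 ± 0.53), a receptor gene of leukocytes, rose as well, with 4AL means of Pnliprp2, Stmn2 and Snap25 below the filter. For Pnpla3, Gzmb, Gzma, Nkg7, Prf1, Siglec10, Myh6, Pnliprp2, Cpa1, the neuronal genes and the 9 skeletal muscle genes named, every animal of at least 1 group lay on the same side of the median of the other group. Per2 rose by 2.36 ± 0.28 and Dbp by 1.91 ± 0.30. Cdkn1a fell by 0.49 ± 0.18, a call that ended in 7 of 19 fits without a single array (highest adjusted p of 0.1 without 28AL animal 8) and under 5 other settings, among them the skeletal muscle term (0.0702, with a larger error at -0.57 ± 0.23) and a block of array numbers (0.0945). Pdk4 (0.20 ± 0.39) did not pass the test, and Nppb and Cdkn2a did not pass the intensity filter in WAT and have no test there.

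In limma, 5970 of 18749 probe sets differed between 28AL and 4AL WAT, 3300 higher and 2670 lower, covering 2012 named genes up and 1893 down. The share of higher probe sets was 55.3%, and 48.4% with equal array medians. Of these probe sets 464 were higher and 524 lower by at least 2-fold. Camera called 26 of 44 lists, 9 up and 17 down, and 0 of them with an estimated correlation. The muscle markers differed between arrays within the 4AL and the 28CR group and with age between groups, so a term for them removes part of the age difference as well.

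**Figure D3:**
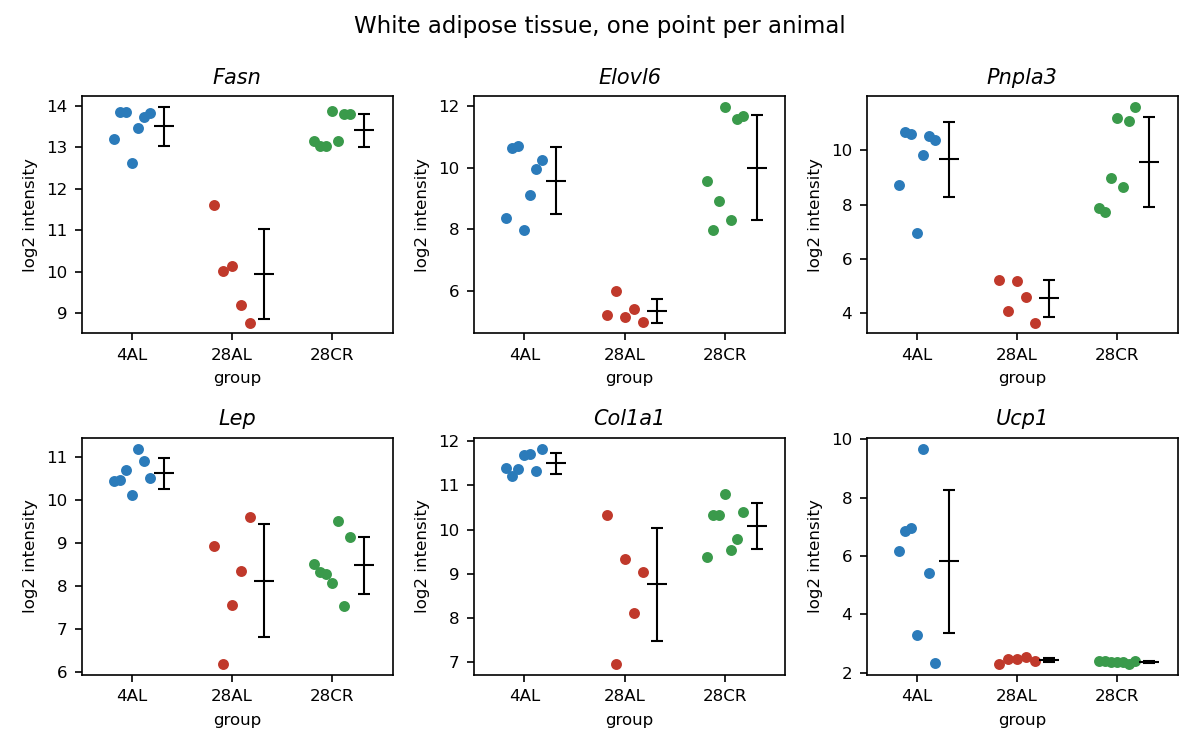
Log2 intensity in WAT of 6 genes, with 1 point per animal and the mean ± SD of each group (7 4AL, 5 28AL and 7 28CR animals). Fasn, Elovl6 and Pnpla3 were lower in 28AL animals than in both other groups, while Lep and Ucp1 were lower in both groups of 28 months and Col1a1 had its lowest mean in 28AL animals.

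The comparison of 28CR with 28AL WAT addressed what caloric restriction changes in aged adipose tissue. Enzymes of lipid synthesis rose. Pnpla3 rose by 5.06 ± 0.72, Elovl6 by 4.64 ± 0.66, Me1 by 3.83 ± 0.57, C5h8orf88 by 3.56 ± 0.61, Fasn by 3.46 ± 0.35, Aacs by 3.39 ± 0.47, Apod by 3.29 ± 0.56, the acetyl-CoA carboxylase gene Acaca by 3.18 ± 0.30, Gpam by 2.93 ± 0.45, Tm7sf2 by 2.93 ± 0.39 and Scd by 2.92 ± 0.54. Fasn had a log2 intensity of 13.41 ± 0.40 (SD, n = 7) in 28CR WAT. Apod and Tm7sf2 had 28AL means below the filter at 4, so their sizes are set against background. For the 10 largest increases and 10 largest decreases, every animal of at least 1 group lay beyond the median of the other. Of 24 lipogenesis genes 23 rose and 0 fell, with a median of 2.27, and of 19 cholesterol synthesis genes 18 rose and 0 fell, among them Acat2 (1.88 ± 0.37), Fdps (1.74 ± 0.35) and Nsdhl (1.67 ± 0.34). The counts adjusted over the list alone were the same for both lists (adjusted p = 1.6e-14 and 2.17e-07; adjusted p = 0.253 and 0.36 with an estimated correlation).

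Mitochondrial and glucose genes rose with restriction in WAT as well. Of 39 genes of oxidative phosphorylation 32 rose and 0 fell (35 and 0 adjusted over the list alone), with Ndufs1 at 0.94 ± 0.12, Ndufs7 at 0.92 ± 0.15 and Ndufs3 at 0.88 ± 0.14. In the TCA cycle list 17 of 18 rose and 0 fell (17 and 0), with Pc at 1.78 ± 0.27, Mpc1 at 1.72 ± 0.30 and Pdhb at 1.56 ± 0.30. The glucose transporter gene Slc2a4 rose by 1.97 ± 0.28, the hexokinase gene Hk2 by 1.97 ± 0.38 and Pfkl by 1.58 ± 0.19, with the 28AL mean of Hk2 at 3.99, and 13 of 20 members of the glycolysis list rose with 0 down (14 and 0). These 3 lists had adjusted p = 6.9e-11, 4.66e-08 and 1.97e-05 (adjusted p = 0.324, 0.253 and 0.253 with an estimated correlation). Beside them the 17 skeletal muscle markers had a median of 2.15 with 0 members called, 0 adjusted over the list alone, and a list adjusted p of 0.276.

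Cardiac transcripts fell in WAT with restriction, with Myh6 at -4.75 ± 0.57, Tnnt2 at -3.63 ± 0.61 and Tnni3 at -2.61 ± 0.58, and Tnni3 at -1.66 without 28AL animal 6. Of the 9 cardiomyocyte markers 6 fell and 0 rose (7 and 0 adjusted over the list alone; adjusted p = 5.9e-05; adjusted p = 0.324 with an estimated correlation). The 28CR means of Myh6, Tnnt2, Grhl3 and Scgb1d2-ps1 lay below the filter, so these sizes are set against background. Grhl3 fell by 3.51 ± 0.55, Siglec10 by 2.72 ± 0.53 and Cpa1 by 2.10 ± 0.28. Scgb1d2-ps1 fell by 2.05 ± 0.77, a call at an adjusted p of 0.0494 that ended in 15 of 19 fits without a single array (highest adjusted p of 0.148 without 28AL animal 10) and under several other settings (0.0516 to 0.0702).

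Macrophage and other leukocyte genes fell with restriction in WAT, among them Gpnmb (-2.0 ± 0.37), the leukocyte genes Lilrb4 (-1.97 ± 0.26), Cd300a (-1.88 ± 0.30) and Cd53 (-1.46 ± 0.17), Cd68 (-1.26 ± 0.26) and Adgre1 (-1.12 ± 0.19), which encodes the F4/80 antigen. Of 16 macrophage markers 10 fell and 0 rose (11 and 0 adjusted over the list alone; adjusted p = 1.88e-07; adjusted p = 0.253 with an estimated correlation). Of 17 MHC genes 8 fell and 0 rose (9 and 0), with RT1-Bb at -0.97 ± 0.16 and RT1-Da at -0.84 ± 0.20 (adjusted p = 1.39e-05; adjusted p = 0.424 with an estimated correlation). Cd74 fell by 0.66 ± 0.20, and this call ended in 2 of 19 fits without a single array (highest adjusted p of 0.0609 without 28AL animal 8) and without both WAT arrays of doubt (0.0828). The chemokine gene Ccl6 fell by 1.37 ± 0.20 and Blnk by 1.30 ± 0.15. Of 15 T cell and NK cell markers 6 fell and 0 rose (7 and 0; adjusted p = 0.000162; adjusted p = 0.36 with an estimated correlation), whereas Gzma differed by -1.25 ± 0.54 without passing the test and passed with the skeletal muscle term (0.0435). With the replicate block the calls ended for RT1-Da (adjusted p = 0.0693), Cd68 (0.0524) and Cd74 (0.138).

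Among the other genes reported in each comparison, Pdk4 fell by 1.42 ± 0.39 (adjusted p = 0.0104, and 0.0523 for the mean of its probe sets) and Timp1 by 0.90 ± 0.23. Col1a1 rose by 1.33 ± 0.39, Cdkn1a by 0.61 ± 0.18, Col3a1 by 0.81 ± 0.24 and Pparg by 0.45 ± 0.16, and Nppa fell by 0.72 ± 0.25. Without 28AL animal 8 the change of Col1a1 was 0.88. The call for Col3a1 ended without 28AL animal 10 (adjusted p = 0.0601) and in a fit of only these groups (0.0521). For Pparg the call ended in 9 of 19 fits without a single array (highest adjusted p of 0.136 without 28AL animal 6, where the difference was 0.29), and under 6 other settings, among them both scalings (0.0745 and 0.0861). Nppa had a 28CR mean of 3.58, below the filter, and its call ended in 5 of the 17 fits in which it passed the filter (highest adjusted p of 0.104 without 28AL animal 6). With the replicate block the calls ended for Col1a1 (0.142), Col3a1 (0.17), Cdkn1a (0.108), Pdk4 (0.0788), Timp1 (0.0596), Nppa (0.0824) and Pparg (0.0825). Lep (0.36 ± 0.42), Ucp1 (-0.06 ± 0.79), Per2 (-0.15 ± 0.28) and Myh7 (-0.02 ± 1.23) did not pass the test. With the skeletal muscle term, whose slope comes from the 4AL and 28CR arrays, Myh7 was 1.71 lower. Adipoq (-0.19 ± 0.08, adjusted p = 0.0723) and Dbp (0.80 ± 0.30, adjusted p = 0.0511) did not pass the test either, and passed without some single arrays, with lowest adjusted p of 0.0293 and 0.0197.

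Limma called 5801 of 18749 probe sets between 28CR and 28AL WAT, 3471 higher and 2330 lower, with 461 higher and 271 lower by at least 2-fold. The calls covered 2618 named genes up and 1285 down, and camera called 17 of 44 lists, 8 up and 9 down, of which 0 were called with an estimated correlation. The share of higher probe sets among the calls, 59.8%, was 47.9% with equal array medians, and with the shared array numbers as a replicate block over 5 arrays of each group 1924 probe sets were called. Restricted animals were also housed singly and fed another diet formula from 4 months, so these differences are part of the comparison.

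**Figure D4:**
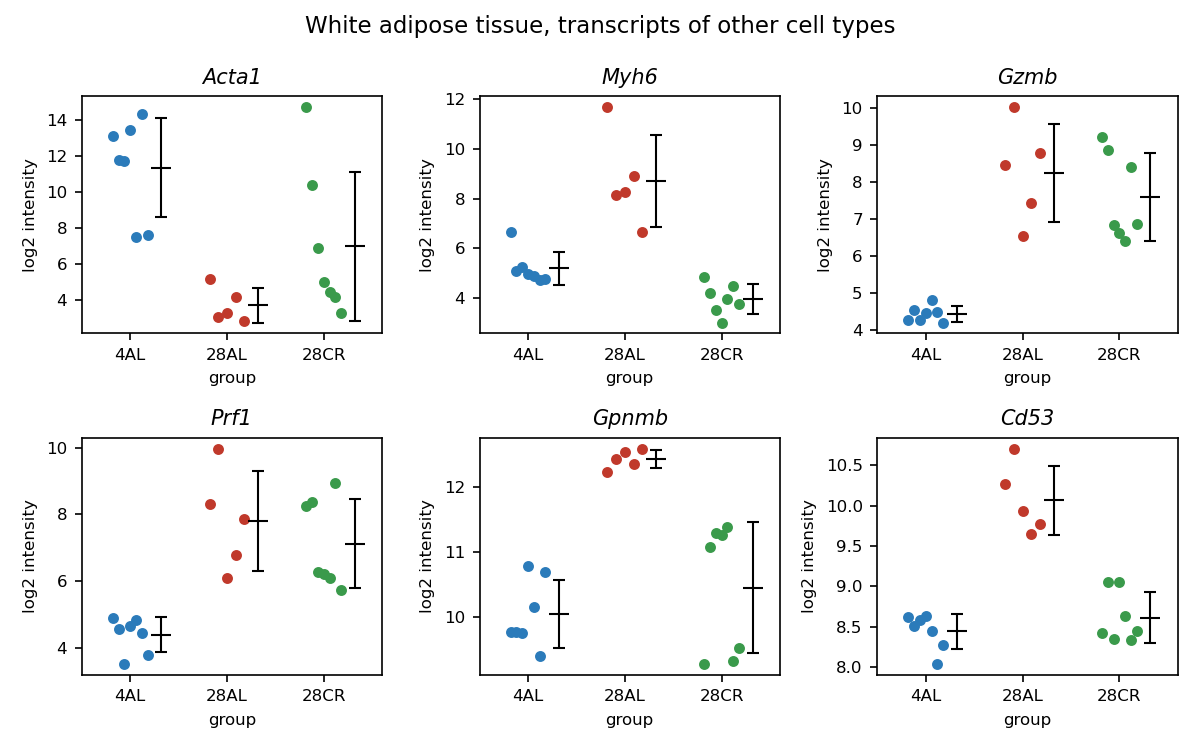
Log2 intensity in WAT of 6 genes of other cell types, with 1 point per animal and the mean ± SD of each group (7 4AL, 5 28AL and 7 28CR animals). Acta1 is a skeletal muscle gene, Myh6 a cardiac gene, Gzmb and Prf1 are genes of cytotoxic lymphocytes, Gpnmb of macrophages and Cd53 of leukocytes. The highest Acta1 value, 14.73, and the highest Myh6 value, 11.67, each belong to 1 array.

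The comparison of 28CR with 4AL WAT addressed whether adipose tissue of restricted animals of 28 months differs from that of young animals. Stmn2 rose by 3.79 ± 0.28, Gzmb by 3.16 ± 0.48, Snap25 by 3.14 ± 0.32, Pnliprp2 by 2.97 ± 0.85, Nkg7 by 2.82 ± 0.62 and Prf1 by 2.72 ± 0.55. Ucp1 fell by 3.45 ± 0.72, the cadherin gene Cdh22 by 3.01 ± 0.20, Obp3 by 2.18 ± 0.29, Lep by 2.14 ± 0.39 and the smooth muscle actin gene Actg2 by 1.98 ± 0.59. All animals of a group lay past the other group's median in each of the 5 largest changes in either direction. The 4AL means of Stmn2, Snap25, Pnliprp2 and Nkg7 and the 28CR means of Ucp1 and Cdh22 lay below the filter, so these sizes are set against background. The call for Actg2 ended in 3 of 19 fits without a single array, with the highest adjusted p of 0.0581 without 4AL animal 18. Fasn (-0.09 ± 0.32) and Scd (-0.33 ± 0.50) did not pass the test, and in the lipogenesis list 2 of 24 members rose and 0 fell (2 and 0 adjusted over the list alone; median 0.21; list adjusted p = 0.955).

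Collagen genes fell in 15 of 27 members with 0 up (15 and 0 adjusted over the list alone), including Col1a1 (-1.42 ± 0.35), Col1a2 (-1.33 ± 0.24), Col12a1 (-1.17 ± 0.15) and Col3a1 (-1.07 ± 0.22). Fibroblast and stromal markers moved with them, with a median of -0.39, 6 of 12 down and 1 up (6 and 1; adjusted p = 6.88e-06; adjusted p = 0.381 with an estimated correlation). Interferon genes fell in 9 of 22 members with 0 up (10 and 0), including Mx1 (-1.47 ± 0.27), Irf7 (-1.37 ± 0.25) and Isg15 (-1.28 ± 0.31). T cell and NK cell markers rose in 10 of 15 members with 0 down (11 and 0). In the glucocorticoid list 10 of 15 members rose and 1 fell (11 and 1), with Ddit4 at 1.84 ± 0.26, Per1 at 1.37 ± 0.23 and Fkbp5 at 1.16 ± 0.29 up, and down Hsd11b1, which encodes the enzyme that regenerates active glucocorticoid, at -1.20 ± 0.20. The lists of collagen, interferon, T cell and NK cell, and glucocorticoid genes had adjusted p = 6.75e-12, 1.3e-09, 0.00142 and 0.00473 (adjusted p = 0.381, 0.381, 0.419 and 0.381 with an estimated correlation). Adrb3 fell by 0.80 ± 0.20, and the thermogenic list was lower with 3 of 9 members down and 0 up (5 and 0; adjusted p = 0.00142; adjusted p = 0.0734 with an estimated correlation). Skeletal muscle markers moved with these lists, with a median of -2.83, 2 of 17 members down and 0 up (1 and 0; adjusted p = 3.68e-08; adjusted p = 0.381 with an estimated correlation). Acta1 fell by 4.38 ± 1.48, a call at an adjusted p of 0.0453 that ended in 14 of 19 fits without a single array (highest adjusted p of 0.0922 without 28CR animal 11) and under 5 other settings (0.0504 to 0.0748).

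Dbp rose by 2.71 ± 0.28 and Per2 by 2.21 ± 0.25 between 4AL and 28CR WAT. Pparg rose by 0.53 ± 0.15, Pdk4 fell by 1.22 ± 0.36 and Adipoq fell by 0.23 ± 0.07. The call for Adipoq ended in 6 of 19 fits (highest adjusted p of 0.0645 without 4AL animal 18) and under 4 other settings (0.0502 to 0.0955), that for Pdk4 without 4AL animal 20 (0.0534) and with the skeletal muscle term (0.0934), and that for Pparg with equal array medians (0.0511) and with the skeletal muscle term (0.0769). Cd68 (-0.32 ± 0.24), Cd74 (0.20 ± 0.19), Cdkn1a (0.12 ± 0.16), Timp1 (-0.23 ± 0.21) and Nppa (-0.43 ± 0.23) did not pass the test. Myh6 (-1.23 ± 0.52) and Myh7 (-1.05 ± 1.12) did not pass it either, while Myh6 passed in a fit of only these groups (adjusted p = 0.0118) and Myh7 was 1.28 higher with the skeletal muscle term (adjusted p = 0.0468) and 2.19 lower without 28CR animal 6 (0.0412).

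Limma called 3409 of 18749 probe sets between 28CR and 4AL WAT, 2366 higher and 1043 lower, and 5982 with array weights. The share of higher probe sets, 69.4%, was 53.4% with quantile normalization and 40.5% with equal array medians. Camera called 13 of 44 lists, 2 up and 11 down, and 0 of them with an estimated correlation.

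The changes with age and with restriction share the 28AL arrays, and their relation addressed how far restriction moves expression against the direction of age. In WAT, 3141 probe sets changed with age and changed the opposite way with restriction, among them those of Fasn, Elovl6, Pnpla3, Myh6, Tnnt2, Gpnmb and Cd53. Of these, 1434 were higher with age and lower with restriction, against 410.1 if the calls were independent, and 1707 were lower with age and higher with restriction, against 494.3. The counts with the same direction were 11 (both higher) and 2 (both lower), against 610.9 and 331.8. Across probe sets, which are not independent replicates, Pearson's r between both changes was -0.73 in WAT and -0.16 in heart, and Spearman's rho -0.70 and -0.18. Shared 28AL arrays alone, with no true change, gave a mean r of -0.56 in WAT and -0.46 in heart over 100 simulations, in which at most 0 and 71 probe sets were called in opposite directions. When the 28AL arrays of WAT were split so that each change had its own arrays, the median of the opposite calls over 20 splits was 1134, from 673 to 1513, and the median r was -0.578. In heart the median of the opposite calls over 70 such splits was 0, from 0 to 55, with 0 to 401 calls for restriction, and r ran from -0.282 to 0.355 with a median of -0.00814. The covariance of both changes was -0.208 in WAT and -0.0093 in heart, against -0.028 and -0.0109 from shared arrays alone. With all arrays, 0 probe sets were called in opposite directions in heart by limma, and 1396 had an unadjusted p under 0.05 for restriction.

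The comparison of the age changes between WAT and heart addressed whether the tissues age alike. Lipogenic genes fell in WAT relative to heart, with Fasn at -3.83 ± 0.42 and Acaca at -3.15 ± 0.33, and so did matrix genes, with Col1a1 at -2.69 ± 0.43, Col14a1 at -2.65 ± 0.23 and Postn at -2.39 ± 0.36. Postn rose in heart and did not pass the test in WAT (-0.05), whereas Col1a1 fell in WAT and did not pass it in heart. Irf7 rose in heart and fell in WAT (-0.83), a difference of -2.17 ± 0.33. Nppa (-2.96 ± 0.30), Gsta1 (-3.18 ± 0.23) and Asns (-3.67 ± 0.24), the asparagine synthetase gene, were also lower in WAT relative to heart. Higher in WAT relative to heart were Myh6 (4.00 ± 0.57), Tnni3 (2.80 ± 0.58), Rab3b (2.73 ± 0.34), the T cell receptor complex gene Cd3g (2.63 ± 0.55), Tnnt2 (2.45 ± 0.61) and Emcn (1.06 ± 0.15). Without WAT 28AL animal 6 Tnni3 was 1.85 and Tnnt2 1.61.

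Of 20 lipogenesis genes measured in both tissues 15 were lower and 0 higher in WAT relative to heart (16 and 0 adjusted over the list alone), of 26 collagen and matrix genes 14 and 0 (16 and 0), of 22 interferon genes 13 and 0 (15 and 1), and of 13 T cell and NK cell markers 0 were lower and 6 higher (0 and 7). Camera called these lists with adjusted p = 2.1e-11, 1e-09, 8.93e-06 and 0.00106 (adjusted p = 0.237, 0.237, 0.307 and 0.309 with an estimated correlation). Fibroblast and stromal markers (median -1.73, 9 of 11 lower and 0 higher, and the same over the list alone) and erythroid and blood markers (median -0.90, 3 of 5 lower and 0 higher, 4 and 0 over the list alone) moved with them (adjusted p = 9.12e-08 and 0.00185; adjusted p = 0.198 and 0.237 with an estimated correlation). So did skeletal muscle genes, with Myl1 at -7.98 ± 1.39, Acta1 at -7.84 ± 1.66, Mybpc2 at -5.82 ± 1.60, Myot at -5.63 ± 1.52 and Tnni2 at -4.74 ± 1.43. With the skeletal muscle term the values were -0.38 for Mybpc2, -0.60 for Myot and 0.15 for Tnni2, and these 3 calls ended. These 3 genes are among the markers whose mean is that term, so it takes out their change by construction. Limma called 3628 of 16684 probe sets for this difference, 1879 higher and 1749 lower. The share of higher probe sets was 51.8%, and 49.9% with equal array medians. Probe sets changed in the same direction with age in both tissues numbered 611 higher and 396 lower, against 343 and 212.3 if the calls were independent. Those changed in opposite directions numbered 196 higher in heart and lower in WAT and 120 lower in heart and higher in WAT, against 272.1 and 267.5.

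The comparison of the restriction changes between WAT and heart addressed whether the tissues respond alike. Pnpla3 (5.04 ± 0.69), Me1 (3.74 ± 0.58), Fasn (3.11 ± 0.41), Gpam (3.04 ± 0.53), Acaca (2.94 ± 0.32) and Tm7sf2 (2.89 ± 0.39) were higher with restriction in WAT relative to heart. Slc2a4 (1.96 ± 0.33), Mpc1 (1.63 ± 0.30) and Ndufs1 (0.93 ± 0.14) were higher as well. Myh6 (-4.92 ± 0.56), Tnnt2 (-3.61 ± 0.60), Tnni3 (-2.60 ± 0.57), Gpnmb (-2.19 ± 0.44), the sodium pump subunit gene Atp1b1 (-2.16 ± 0.31) and Cd68 (-1.5 ± 0.32) were lower, with Tnni3 at -1.65 without WAT 28AL animal 6. Of 20 lipogenesis genes 19 were higher and 0 lower (19 and 0 adjusted over the list alone), of 39 genes of oxidative phosphorylation 24 and 0 (29 and 0), and of 16 macrophage markers 0 were higher and 6 lower (0 and 9). Camera called these 3 lists with adjusted p = 3.16e-17, 6e-12 and 8.98e-08 (adjusted p = 0.179, 0.225 and 0.225 with an estimated correlation). Limma called 2360 of 16684 probe sets, 1451 higher and 909 lower.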

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

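The tests of skeletal muscle pieces, of age alone, of heart RNA and of blood were chosen only after the results were seen, as were the skeletal muscle term and the fits without arrays of doubt; the tests of heart RNA and of age alone were also altered after their first values were seen.

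Skeletal muscle transcripts in WAT differed between single arrays, with Acta1 at a log2 intensity of 14.73 in 28CR animal 6 and from 2.83 to 5.17 in the 28AL arrays. Pieces of skeletal muscle in the samples may be the source: over the 19 WAT arrays, centred by group, the median correlation of each of the 17 markers with the mean of the others was 0.991 (Spearman's rho 0.966; permutation p = 1e-04 for each, the smallest they can give), and 0.981 without 28CR animal 6 and 4AL animal 21, with -0.0452 for Myh1 as the lowest. The permutations shuffled each marker alone, so their p speaks only to the markers varying together, whatever the source of the RNA. Of the 17 markers 4 are in another list, and 16 had a mean log2 intensity of at least 6 in 4AL WAT and 1 in 28AL WAT. Age of the animals alone is argued against for the spread among arrays of animals of the same age. Marker means ran from 5.11 to 12.23 in 4AL and from 3.89 to 13.2 in 28CR WAT. For the difference between 4AL and 28AL arrays age is not excluded, since every 4AL array lay above every 28AL array (3.86 to 4.13). The 7 4AL arrays that lay below the highest array of the animals of 28 months rest on 28CR animal 6, without which 2 did. A further condition, that the order hold without the highest array and against 28AL arrays alone, was added after the value of 7 was seen. The fall of lipogenic genes with age in WAT did not shrink with the skeletal muscle term (median -2.27 against -1.69 without it). The term's slope is from the 4AL and 28CR arrays, so skeletal muscle RNA as the cause is undecided. Differences between groups in dissection or muscle stay open and untested.

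Cardiac transcripts rose in WAT of 28AL animals, with Myh6 at 11.67 in animal 6 and from 6.64 to 8.91 in the other 28AL arrays. Heart RNA carried into the WAT samples could not be decided: with the median share of the heart level over the cardiomyocyte list, 35.5% of 31 other genes abundant in heart and low in WAT reached at least 50% of the level needed, and 36.7% of 30 with 4AL in place of 28AL hearts, between the bounds for either answer, which were kept from the first form of the test. Of the 2 genes as abundant in heart as that list 50% did, and 100% with 4AL hearts. The first form took the share from Myh6 alone, and 0% of 40 genes reached the level. A later form took it from the median of the tested genes themselves and was dropped as circular. In animal 6 the shares of single genes ran from 0.135% for Nppa to 13.6% for Myh6. Of the 9 cardiomyocyte markers measured all 9 are in another list. Expression in cells of aged WAT, and cardiac muscle from elsewhere in the animal, stay open and untested.

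Cytotoxic lymphocyte transcripts rose with age in both tissues. More blood in the samples of old animals is argued against in WAT, where the median change of the erythroid markers was 0.39 and that of 5 cytotoxic genes 3.51, but may be the source in heart, where they were 1.91 and 1.54. Other leukocyte lists in heart went both ways with age. Neutrophil and mast cell markers had a median of 1.22, and B cell and plasma cell markers, a list that was not called, one of -0.22. A cytotoxic cell population carried by single animals, such as the large granular lymphocyte leukemia to which aged F344 rats are prone, could not be decided: the cytotoxic score of heart and WAT arrays with 1 number, centred by group, had a Pearson's r of 0.514 (permutation p = 0.0977) and a Spearman's rho of 0.476 (permutation p = 0.124) over 12 numbers, and r was 0.228 without the 2 farthest. Over the 7 28CR numbers alone r was 0.216 (permutation p = 0.623; rho 0.321, permutation p = 0.498) and -0.252 without the 2 farthest. Over the 5 28AL numbers, fewer than the 6 set here for giving a correlation, r was 0.899 and was not tested. The numbers are not shown to stand for 1 animal, which keeps it open. An increase of such cells with age in the tissues may also be the source and was not tested, and 0 of the 15 T cell and NK cell markers in WAT are in another list.

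A single array lay far from the others of its group in 45 of 570 groups of arrays, against 28.5 that chance gives at about 1 in 20, judged by the gap to the nearest array as a share of the range of the group. In heart, animal 8 of the 28AL group did so for 6 genes, at 0.682 for Cd163, 0.704 for Asns and 0.8 for Nfil3 (highest) and 0.621 for Hadh, 0.702 for Sucla2 and 0.617 for Ndufs1 (lowest). Animal 7 of that group was lowest for Pdk4 (0.592) and Ddit3 (0.6). In the 4AL hearts animal 20 was highest for Timp1 (0.642), S100a8 (0.828), Pdk4 (0.679) and Nfil3 (0.734), animal 18 lowest for Aqp7 (0.878), Ndufa9 (0.682) and Col1a1 (0.682), and animal 17 highest for Cnpy1 (0.649). Among 28CR hearts, animal 8 was highest for Cxcl13 (0.646), Fasn (0.772) and Per1 (0.694), animal 6 highest for Nr4a1 (0.643), Trib3 (0.745) and Krt19 (0.609), animal 11 lowest for Gsta1 (0.665) and animal 12 lowest for Myh7 (0.585).

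In WAT, 28AL animal 6 was farthest for 5 genes on the high side, Myl11 (0.742), Ckm (0.822), Tnni3 (0.834), Tnnt2 (0.803) and Irf7 (0.774). In the same group animal 9 was highest for Emcn (0.83) and lowest for Cd300a (0.743), and animal 10 lowest for Me1 (0.862). In 4AL WAT animal 17 was highest for Myh6 (0.723), Gzma (0.595) and Scgb1d2-ps1 (0.697), animal 20 lowest for Ndufs3 (0.743) and Slc2a4 (0.574), and animal 18 lowest for Col12a1 (0.582). In 28CR WAT animal 6 was highest for Tnnt3 (0.574), Cdh22 (0.593) and Myh7 (0.749), animal 7 highest for Gzma (0.596), animal 9 lowest for Pdk4 (0.603) and highest for C3 (0.741), and animal 12 highest for Scgb1d2-ps1 (0.945).

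The changes differed between WAT and heart by the interaction test for 3628 probe sets with age and 2360 with restriction. The differences with age (WAT minus heart, log2) were 4.00 for Myh6, 2.80 for Tnni3, 2.73 for Rab3b, 2.63 for Cd3g, 2.45 for Tnnt2 and 1.06 for Emcn, and -7.98 for Myl1, -7.84 for Acta1, -5.82 for Mybpc2, -5.63 for Myot, -4.74 for Tnni2, -3.83 for Fasn, -3.67 for Asns, -1.25 for Ddit3, -1.26 for Trib3, -3.18 for Gsta1, -3.15 for Acaca, -2.96 for Nppa, -2.69 for Col1a1, -2.65 for Col14a1, -2.39 for Postn and -2.17 for Irf7. With restriction they were 5.04 for Pnpla3, 3.74 for Me1, 3.11 for Fasn, 3.04 for Gpam, 2.94 for Acaca, 2.89 for Tm7sf2, 1.96 for Slc2a4, 1.63 for Mpc1 and 0.93 for Ndufs1, and -4.92 for Myh6, -3.61 for Tnnt2, -2.60 for Tnni3, -2.19 for Gpnmb, -2.16 for Atp1b1 and -1.5 for Cd68.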

How the results depend on the processing

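The skeletal muscle term and the fits without arrays of doubt were chosen after the data were seen, and the other alternatives before. Counts of called probe sets are compared with a margin of 1.5 times. Without an intensity filter, with the stricter filter, no trend, robust moderation, either scaling, only the groups compared or a block of array numbers, the total counts stayed within that margin of the values in the report, and so did those with the skeletal muscle term and without the arrays of doubt. The counts by direction did not all do so: for 28CR against 4AL in WAT 2366 higher became 1206 with equal medians and 1485 with quantile normalization, and 1043 lower became 1774 with equal medians. Without a filter 2330 lower with restriction in WAT became 4131, and 1879 higher in the difference of age changes between tissues became 3312.

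With a minimum change of 1.5-fold, which by construction calls fewer, the counts were 1452 for age and 1505 for 28CR against 4AL in heart, and 3113 for age, 2913 for restriction, 1364 for 28CR against 4AL and 1484 for opposite changes in WAT. With 1 probe set per gene and with the mean of the probe sets of a gene, where fewer features are tested, they were 3315 and 3284 for age in WAT, 3532 and 3538 for restriction, 2157 and 2088 for 28CR against 4AL, 1832 and 1805 for opposite changes, 2138 and 2135 for the difference in age changes between tissues and 1564 and 1567 for that in restriction changes. Array weights gave 3 for restriction in heart and 1 for opposite changes there, where limma without them called 0 (1396 at an unadjusted p under 0.05), and 5982 for 28CR against 4AL in WAT; the cause was not tested. With the replicate block, which also uses fewer arrays, restriction called 1924 probe sets in WAT and 0 in heart (1396 at an unadjusted p under 0.05 without it). The effects of the block and of fewer arrays were not separated. Splitting the 28AL arrays of WAT gave a median of 1134 opposite changes, also from fewer arrays per comparison.

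Leaving out each array in turn gave from 3022 to 4022 for age, 0 to 2 for restriction and 3254 to 4255 for 28CR against 4AL in heart, with 0 to 0 opposite changes in limma (1396 at an unadjusted p under 0.05 for restriction with all arrays). For heart restriction 2 were called without 28AL animal 8 and 1 without 28CR animal 6 or 28CR animal 11. In WAT the counts ran from 4960 to 6336 for age, 4422 to 5835 for restriction, 2422 to 3858 for 28CR against 4AL and 2306 to 3281 for opposite changes. Between tissues they ran from 3069 to 3961 for age and from 1685 to 2677 for restriction.

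The results that reversed did so with the skeletal muscle term, in genes of muscle. Ckm was 0.34 for age in WAT, and Myh7 2.99 for age and 1.28 for 28CR against 4AL in WAT. In the difference of age changes between tissues Tnni2 was 0.15, Pgam2 0.48, Eno3 1.33 and Ckm 0.99. The term takes out what goes with skeletal muscle transcripts by construction. Ckm, Tnni2 and Eno3 are also among the markers in it. For Myh7 in 28AL WAT the value with the term rests on the slope in the 4AL and 28CR arrays.

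Of the values of single named genes under the alternatives, 3869 of 3981 for age, 1956 of 1959 for restriction and 3205 of 3268 for 28CR against 4AL in heart kept their side of the threshold, with the same direction if called. In WAT 3596 of 3659, 2692 of 2917 and 1961 of 2068 did so, and for the differences between tissues 3725 of 3825 with age and 2729 of 2794 with restriction. Direction was not compared for a gene called in neither fit. For restriction in heart 0 of the 62 named genes were called, so its values speak only to staying uncalled. Of list results, 152 calls ended with an estimated correlation and 198 results kept their side. With fry 278 kept their side, 30 calls ended and 42 were gained, and with the mean of probe sets 338 kept it, 5 ended and 7 were gained.

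Arrays that share only a number in the labels were compared by the correlation of their centred profiles, as a check of pairing. It ran from -0.39 to 0.48 over 7 pairs of 28AL and 28CR hearts, from -0.13 to 0.15 over 5 pairs in WAT and from -0.19 to 0.2 over 18 pairs of heart and WAT. Signal over background limits genes near the filter: between 56.1% and 59% of probe sets per array reached a log2 intensity of 4, and a change of a gene below it is set against background.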

Other observations

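The count of unadjusted p values in splits of the hearts was chosen only after the result was seen, and the other splits before. The genes of the next paragraphs outside the naming rule were chosen after their values were seen.

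Genes of the circadian clock differed between ages in both tissues and in both feeding groups. Bmal1, which encodes the main activator of the clock, was lower in 28AL than in 4AL animals by -1.28 ± 0.24 in heart and -1.22 ± 0.19 in WAT, and in 28CR than in 4AL animals by -1.51 ± 0.24 and -1.08 ± 0.18. In heart Cry1 (-1.08 ± 0.19) and Nfil3 (-0.75 ± 0.15) fell with age, and Per2 (1.59 ± 0.22), Per1 (0.81 ± 0.18) and Bhlhe41 (0.79 ± 0.17) rose. In WAT Per2 (2.36 ± 0.28), Dbp (1.91 ± 0.30), Per3 (1.66 ± 0.23), Bhlhe41 (1.51 ± 0.24), Nr1d1 (1.21 ± 0.22), Nr1d2 (1.11 ± 0.15) and Per1 (1.09 ± 0.25) rose. The circadian list was not called for age in heart (adjusted p = 0.551; 6 of 16 members higher and 5 lower) or WAT (adjusted p = 0.113; 9 of 17 higher and 5 lower). The labels give no time of collection, so age and time of day cannot be separated.

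Asns rose with age by 2.69 ± 0.19 in heart and fell by 0.99 ± 0.14 in WAT, and Ddit3 rose by 0.56 ± 0.10 in heart and fell by 0.70 ± 0.13 in WAT. Trib3 rose by 0.96 ± 0.17 in heart and differed by -0.30 ± 0.18 in WAT without passing the test. The differences between tissues passed the interaction test for Asns (-3.67 ± 0.24), Ddit3 (-1.25 ± 0.16) and Trib3 (-1.26 ± 0.25). In the list of ER stress that holds them, 6 of 23 members were lower and 1 higher in WAT relative to heart (8 and 1 adjusted over the list alone; adjusted p = 0.00148; adjusted p = 0.285 with an estimated correlation). In 28CR against 4AL hearts Asns rose by 3.00 ± 0.19, Trib3 by 1.30 ± 0.17 and Ddit3 by 0.79 ± 0.10. In WAT Asns rose by 0.84 ± 0.14 with restriction, whereas Trib3 fell by 0.58 ± 0.18.

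Whether chance alone gives as many calls was tested with 100 splits of the arrays into groups of the real sizes, the real split included. Chance can be excluded in heart for age (3702 against at most 833 in other splits) and 28CR against 4AL (4002 against 1035). In WAT it can for age (5970 against 639), restriction (5801 against 2001) and 28CR against 4AL (3409 against 179). Opposite changes in WAT gave 3141 against 0, and tissue differences 3628 against 1913 (age) and 2360 against 765 (restriction). Those splits remove every group effect, so they exclude only a lack of any change. In each, only the real split of 100 gave as many. For restriction in heart chance cannot be excluded: the real split gave 1396 probe sets at an unadjusted p under 0.05, and 17 of 100 splits gave at least as many, with 2506 as the highest. The counts of calls in heart decide nothing, since the real count was 0 in limma for restriction and for opposite changes, and all 100 splits give at least 0 whatever the data. The highest of the other splits were 109 and 0, and the split with 109 calls may point to a structure of the samples, which was not tested.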
